A study of Mus musculus with 9 samples.

How the data were processed

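RNA was sequenced from mesenchymal stromal cells sorted from the long bones of mice in 3 groups, 3 libraries each. Per the labels' protocols, the mice received an antibody against VE-cadherin, an endothelial surface protein, by retro-orbital injection 10 minutes before death. Cells were then sorted into lysis reagent, and libraries were made from 2 ng of total RNA with SMART-Seq v4. The gates of the sort are not given in the sources used here. The deposited table gives FPKM per gene, fragments per kilobase of transcript scaled to a fixed number of mapped fragments, as the file headers and values show, rounded to 2 decimals. The submitters' processing notes name FastQC 0.11.5, STAR and edgeR and the build GRCm38 (mm10), without the role of each. The annotation, the read counter and the treatment of multi-mapping reads are not given in the sources used here. FPKM scales each library to its own total, so that a few very abundant genes lower the values of all others.

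Sample groups came from the genotype label and columns were matched to samples by title. Gene symbols were matched to GENCODE M21, which gave a model for 30192 of 30579 genes (98.7%). The step between low FPKM values, times the gene's length, gave the number of reads behind each library's scaling. The step was sought only within a window set beforehand, so depths outside that window were not tried. At the step found, 78.3% to 85.6% of low values were whole reads within 0.1, for an estimate of 17.7 to 27.6 M reads (M, mega). That share cannot tell this step from a multiple of it outside the window, which would mean fewer reads. For a gene of 2 kb, 3 reads came to 0.0543 to 0.0845 FPKM. These floors cover counting error only. The share of reads in immunoglobulin genes was estimated from FPKM times gene length. No mitochondrially encoded gene was in the table.

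All tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend, on the 11988 genes with an FPKM of at least 1 in at least 3 libraries. All 9 libraries entered 1 fit with group means and no covariate, leaving 6 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, with a threshold of 0.05. A fold change on this scale understates the change of low genes. Values are group means of FPKM ± SD (n = 3). Thbs1 was also tested by an exact two-sided permutation test. Gene lists, 33 in number, covered stromal, signalling, metabolic and stress programmes, markers of other cell types and signs of RNA quality. The 28 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. The others, endothelial, T and NK, Schwann cell, skeletal muscle and mitochondrially encoded lists, had 3, 2, 3, 2 and 0 tested members and were not tested.

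Groups, tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule took Thbs1 and, among passing genes with an established symbol, no overlap between the groups and a mean of at least 2 FPKM, the 8 largest rises and 8 largest falls. Where fewer than 5 genes passed, it added the 10 smallest p-values. It also took the 4 members with the smallest p of each list that passed, Cxcl12, Kitl, Lepr, Vcam1, Il7 and Cd47 in every comparison, and the 8 genes with the strongest opposite calls in the first 2 comparisons. The text names a part of these. Correlation of fold changes was set beside 100 simulations in which residuals, resampled by library with replacement, gave unchanged groups that share the aged controls.

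The procedure was tested on simulated data for each comparison, with 200 of 11988 genes changed. Of 50 genes changed by 1 on the log2 scale, 2%, 6% and 10% were called in aged against young controls, in labelled-knockout libraries against aged controls and against young controls. At 2 the shares were 74%, 66% and 64%, and at 3 they were 88%, 88% and 98%. Of the calls, 3.82%, 3.05% and 4.93% were unchanged genes. Changes of 2-fold were thus mostly below reach. The simulated noise was independent between genes and had the same spread in every library, and only genes above a minimum level were changed. The rates therefore do not cover shifts shared by many genes, or a library that stands apart, as in the real data.

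Alternatives were a pseudocount of 0.1, no filter, a minimum of 5 FPKM, median-ratio rescaling, quantile normalization, no trend, array weights, a fit of only the compared groups, the replicate number as a block, and each library left out in turn. A further 2 were added after the data were seen. A count-based test was not run, since the values are not counts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for depth estimates and figures.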

Results

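Gene expression was measured by RNA sequencing in mesenchymal stromal cells sorted by flow cytometry from mouse bone marrow. These are the fibroblast-like support cells of the marrow, which make much of the Cxcl12 and Kit ligand that blood stem cells depend on. The series held 9 libraries in 3 groups of 3. Young controls were 3 months old, aged controls were 18 months old, and the mice given as aged Thbs1 knockouts were also 18 months old. Thbs1 encodes thrombospondin-1, a secreted matrix glycoprotein that binds Cd47 and activates latent TGF-beta. Values were FPKM for 30579 genes. Low FPKM values rose in steps that, within the window of depths searched, correspond to 17.7 to 27.6 M reads (M, mega) per library. Between 13503 and 18382 genes were above 0 in a library. The labels do not say whether the 3 libraries of a group came from separate mice, so p-values measure only the spread between these libraries.

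Libraries within the young and aged control groups correlated at 0.957 to 0.987 and 0.907 to 0.956 (log2 values across genes, which are not independent replicates). Replicate 2 of the libraries labelled aged Thbs1 knockout stood apart, with correlations of 0.738 to 0.811 to every other library and the fewest genes above 0, 13503. Immunoglobulin genes took 0.00481%, 0.0129% and 0.216% of reads in the 3 young controls. They took 25.9%, 5.29% and 37.0% in the 3 aged controls, and 0.203%, 23.1% and 2.94% in the 3 libraries labelled knockout. The kappa constant gene Igkc was the most abundant gene in all 3 aged controls and in replicates 2 and 3 of the libraries labelled knockout.

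The targeted gene checks the labels. Thbs1 (ENSMUSG00000040152.8, chromosome 2, 118111876 to 118127133, forward strand, GRCm38) was at 74.98, 73.11 and 58.03 FPKM in young controls and at 35.56, 41.89 and 36.85 FPKM in aged controls. In the libraries labelled aged Thbs1 knockout it was at 24.28, 44.55 and 37.05 FPKM. The means were 68.7 ± 9.29, 38.1 ± 3.35 and 35.3 ± 10.2 FPKM (SD, n = 3 each). The labelled-knockout libraries thus held 92.6% of the aged control level. The log2 fold change against aged controls was −0.15 (SE 0.26, 95% interval −0.72 to 0.43, limma adjusted p = 0.801). The exact two-sided permutation p was 0.9, where 3 against 3 libraries cannot go below 0.1. Over 20 alternatives the log2 fold change ranged from −0.63 to 0.0939 and passed in none. It was 0.0939 without replicate 1 of these libraries, −0.33 without their replicate 2, −0.39 under quantile normalization and −0.63 (adjusted p = 0.0894) with median-ratio rescaling and no replicate 2, an alternative added after the data were seen. A gene-level FPKM does not test a disrupted allele that is still transcribed, and an annotated gene, Gm29233, overlaps Thbs1. A lower level of Thbs1 RNA was therefore not shown for these libraries, and this group is called the libraries labelled aged Thbs1 knockout, or the labelled-knockout libraries, throughout. Aged controls lay below young controls in all 3 libraries by −0.83 on the log2 scale (SE 0.26), which did not pass adjustment (limma adjusted p = 0.107).

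**Figure D1:**
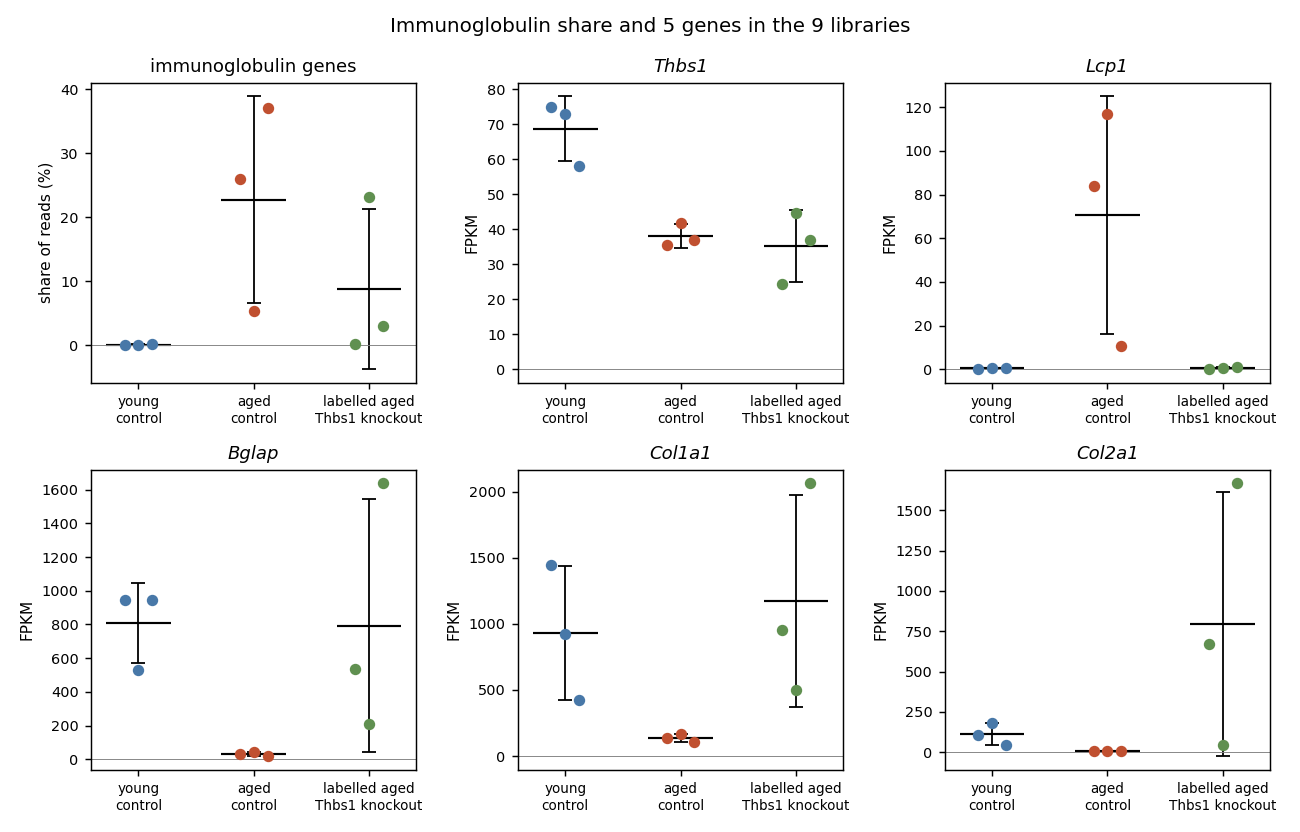
Share of reads in immunoglobulin genes (%) and FPKM of Thbs1, Lcp1, Bglap, Col1a1 and Col2a1 in each of the 9 libraries (points), with the group mean (line) and SD (bar, n = 3) on linear axes. Thbs1 averaged 38.1 FPKM in aged controls and 35.3 FPKM in the labelled-knockout libraries, while Lcp1 averaged 70.5 and 0.707 FPKM.

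The comparison of aged with young controls asks what changed in marrow stromal libraries with age. Some bone-forming and matrix genes were lower in aged controls (10 of 22 and 4 of 34), and pan-leukocyte and B lineage markers were higher (8 of 11 and 6 of 10). No list was called with an estimated correlation, and erythroid (adjusted p = 0.0501), neutrophil (0.0873), monocyte (0.416) and megakaryocyte lists (0.376) were not called at the preset correlation either. Still, 2 of 13 neutrophil and 1 of 5 megakaryocyte markers rose, and no member of either list passed as lower. Most members had negative fold changes, 8 of 13 and 3 of 5, with medians of −0.13 and −0.06. With immunoglobulin genes left out and the libraries rescaled, 5 of 22 osteogenic and 2 of 34 matrix genes fell. The immediate early and sorting stress list, which is sensitive to cell handling, was not called with age (median −0.40, adjusted p = 0.258), but 4 of its 24 members fell (5 adjusted over the list alone). Bglap and Bglap2, which encode osteocalcin, the abundant non-collagen protein of bone, fell from 808 ± 239 to 30.5 ± 11.4 FPKM and from 699 ± 189 to 27.0 ± 8.67 FPKM (SD, n = 3). Their log2 fold changes were −4.70 (SE 0.65, adjusted p = 0.0107) and −4.66 (SE 0.59, adjusted p = 0.00781). The copies are near-identical, so reads between them are uncertain. Col1a1, the main collagen of bone, fell from 931 ± 510 to 135 ± 30.7 FPKM (log2 fold change −2.63, SE 0.57, adjusted p = 0.039). In the other direction Lcp1, an actin-bundling protein of leukocytes, rose from 0.437 ± 0.146 to 70.5 ± 54.4 FPKM (log2 fold change 5.09, SE 0.73, adjusted p = 0.0121).

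Of 11988 genes tested, 484 passed an adjusted p under 0.05 in limma, 308 higher and 176 lower in aged controls. A further measure of separation was that the 3 libraries of each group did not overlap for 44.4% of tested genes, where chance gives 10%. Only 7.02% of tested genes lay higher in all 3 aged controls, where chance gives 5%, so most of the genes without overlap lay lower. The chance values take no account of a shift shared by all genes of a library, so this measure does not count separate gene changes. The count of passing genes changed with the library left out. It came to 31, 36 and 17 genes without young control replicate 1, 2 or 3, to 4 and 197 genes without aged control replicate 1 or 2, and to 2729 genes without replicate 2 of the labelled-knockout libraries, which share the estimate of spread. It moved less without aged control replicate 3 (356) and without replicate 1 or 3 of the labelled-knockout libraries (481 and 337). The median gene lay at −0.28 on the log2 scale, and median-ratio rescaling, which moved that median to 0.00, called 344 genes higher and 65 lower. The balance was the opposite without replicate 2 of the labelled-knockout libraries (611 higher, 2118 lower), in a fit of the 6 libraries alone (546 and 1609), with array weights (1622 and 5797) and with a minimum of 5 FPKM (168 and 201). Which direction held more genes thus depended on the processing. Of the 9 fits without 1 library, the calls of Bglap and Bglap2 were lost in 3, that of Col1a1 in 6 and that of Lcp1 in 4, with no change of direction over 20 alternatives (Bglap −4.97 to −4.32, Col1a1 −3.12 to −2.23, Lcp1 4.45 to 6.50).

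Of 22 tested osteogenic genes 10 fell and none rose (18 fell adjusted over the list alone; camera adjusted p = 8.275e-09, adjusted p = 0.366 with an estimated correlation). Besides Bglap and Col1a1 these included Wif1, a Wnt inhibitor, at 122 ± 15.8 against 26.8 ± 3.82 FPKM, and Spp1 (osteopontin), at 3626 ± 531 against 929 ± 307 FPKM. Among niche factors, the secreted and surface proteins that act on blood stem cells, 5 of 20 fell (16 adjusted over the list alone; adjusted p = 1.354e-06, adjusted p = 0.366 with an estimated correlation). Igf1 fell by 1.72 (SE 0.23), Angptl4 by 2.07 (SE 0.38) and Bmp4 by 1.74 (SE 0.34) on the log2 scale. Vcam1 lay at −1.36 (SE 0.39, adjusted p = 0.0935), Il7 at −1.20 (SE 0.29, adjusted p = 0.0533), Kitl at −0.83 (SE 0.25, adjusted p = 0.104), Cxcl12 at −0.65 (SE 0.29, adjusted p = 0.235) and Lepr at −0.49 (SE 0.33, adjusted p = 0.418). None of these 5 passed. Cd47, a Thbs1 receptor, lay at −0.13 (SE 0.25, adjusted p = 0.799) and turned to 0.21 under median-ratio rescaling. Among extracellular matrix genes 4 of 34 fell (11 adjusted over the list alone; adjusted p = 1.159e-05, adjusted p = 0.584 with an estimated correlation), with Col1a2 at −1.94, Col5a2 at −1.51 and Bgn at −1.02 on the log2 scale. In the 9 fits without 1 library, the calls of Bgn were lost in 8, of Col1a2 in 7, of Wif1, Spp1, Angptl4 and Col5a2 in 6 and of Igf1 and Bmp4 in 4.

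Of 21 adipogenic genes 3 fell (5 adjusted over the list alone; adjusted p = 0.0147, adjusted p = 0.584 with an estimated correlation). They were Lpl, which releases fatty acids from lipoproteins, at 388 ± 43.5 against 135 ± 10.5 FPKM, Adipoq (adiponectin) at 2171 ± 517 against 848 ± 134 FPKM, and Cfd (adipsin) at 16.5 ± 12.2 against 1.09 ± 0.682 FPKM. Pparg, the master regulator of fat cells, lay at −1.52 (SE 0.37, adjusted p = 0.0534). The senescence and secretory list was also lower (2 of 21 fell, and 2 rose and 11 fell adjusted over the list alone; adjusted p = 0.018, adjusted p = 0.584 with an estimated correlation), through Ccl2, a monocyte chemokine, at 275 ± 88.2 against 65.1 ± 27.1 FPKM and Cdkn1a (p21, a cell-cycle inhibitor) at 146 ± 25.2 against 46.8 ± 15.3 FPKM. The stromal identity list was lower as a whole (1 rose and 7 fell adjusted over the list alone; adjusted p = 0.012, adjusted p = 0.584 with an estimated correlation), with 1 member falling, Hoxa10, and 1 rising, Ly6a (Sca-1), from 17.0 ± 6.28 to 438 ± 266 FPKM. Ly6a is also made by blood cells. Pericyte genes (1 of 11 fell, Mylk, 3 adjusted over the list alone; adjusted p = 0.0147, adjusted p = 0.596 with an estimated correlation) and chondrocyte genes (none of 12 passed, 4 fell adjusted over the list alone; adjusted p = 0.0326, adjusted p = 0.596 with an estimated correlation) were lower, the latter with Sox9 at −1.64 (SE 0.43) and Col2a1 at −3.43 (SE 1.09). Oxidative phosphorylation genes were lower (none of 36 passed, 0 adjusted over the list alone; adjusted p = 0.045, adjusted p = 0.596 with an estimated correlation), a call that ended under median-ratio rescaling (adjusted p = 0.272), quantile normalization (adjusted p = 0.398) and with immunoglobulin genes left out (adjusted p = 0.294). Without 1 library at a time, the calls of Adipoq were lost in 8 of 9 fits, of Ly6a in 7, of Cfd in 6, of Ccl2, Cdkn1a and Mylk in 5 and of Lpl and Hoxa10 in 4.

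Of 11 tested pan-leukocyte markers 8 rose (10 adjusted over the list alone; adjusted p = 4.968e-18, adjusted p = 0.189 with an estimated correlation). Besides Lcp1 these included Laptm5, at 58.0 ± 45.8 against 0.677 ± 0.205 FPKM, Spi1 (PU.1) at 17.7 ± 12.2 against 0.26 ± 0.137 FPKM and Cd37 at 15.8 ± 6.44 against 0.227 ± 0.142 FPKM. Of 10 B lineage markers 6 rose (10 adjusted over the list alone; adjusted p = 4.150e-15, adjusted p = 0.189 with an estimated correlation), among them Mzb1 and Cd79a, at 26.2 ± 19.6 and 27.5 ± 15.5 FPKM in aged against 0.02 ± 0.0346 and 0.403 ± 0.0737 FPKM in young controls. Of the 308 genes that rose, 32 were immunoglobulin genes, and Igkc averaged 139025 ± 93756 against 531 ± 819 FPKM. Variable and constant immunoglobulin genes are families of near-identical copies, so reads of single members are uncertain. Unfolded protein response genes rose as a list (1 of 21 passed, Edem1, log2 fold change 3.05, SE 0.63, 7 rose adjusted over the list alone; adjusted p = 3.697e-09, adjusted p = 0.189 with an estimated correlation), as did antigen presentation genes (2 of 14, Cd74 and H2-Ab1, 2 adjusted over the list alone; adjusted p = 0.0157, adjusted p = 0.189 with an estimated correlation), whose median was −0.01 while their mean was 0.60. Mean log2 levels of the unfolded protein response list were 6.73, 6.01 and 7.04 in the 3 aged controls (5.66 to 5.68 in young controls). They followed the order of the immunoglobulin share, 25.9%, 5.29% and 37.0% of reads. The list shares Xbp1 with the plasma-cell markers used below, and whether plasma cells brought this rise was not tested. Cell cycle genes were higher without a member passing (0 of 21, 0 adjusted over the list alone; adjusted p = 4.464e-05, adjusted p = 0.596 with an estimated correlation), with Mcm6 at 0.93 (SE 0.39). Aged control replicate 1 stood out here, with a mean log2 level of 2.99 against 1.77 and 2.02 in replicates 2 and 3 and 1.69 to 1.94 in young controls. Fry did not call the list (adjusted p = 0.570). Over the 9 fits without 1 library, the calls of H2-Ab1 were lost in 8, of Igkc in 7, of Cd74, Edem1, Laptm5 and Spi1 in 5, of Mzb1 and Cd79a in 4 and of Cd37 in 1.

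The comparison of the labelled-knockout libraries with aged controls asks what loss of Thbs1 changes at equal age, although Thbs1 RNA did not separate the groups. Some cartilage (6 of 12), bone (6 of 22), contractile (3 of 11) and early-response genes (5 of 24) were higher in the labelled-knockout libraries, and 7 of 11 pan-leukocyte markers were lower. No list was called with an estimated correlation. Cnmd (chondromodulin), Snorc and Col2a1, genes of cartilage, rose from 0.55 ± 0.641 to 175 ± 195 FPKM, from 0.867 ± 0.18 to 135 ± 130 FPKM and from 8.08 ± 0.217 to 793 ± 817 FPKM (SD, n = 3). Their log2 fold changes were 5.75 (SE 1.13, adjusted p = 0.0318), 5.62 (SE 0.81, adjusted p = 0.0141) and 5.37 (SE 1.09, adjusted p = 0.0337). Atf3, a stress-induced transcription factor, rose from 22.9 ± 2.51 to 184 ± 46.3 FPKM (log2 fold change 2.93, SE 0.27, adjusted p = 0.00191), and Lcp1 fell from 70.5 ± 54.4 to 0.707 ± 0.521 FPKM (log2 fold change −4.88, SE 0.73, adjusted p = 0.017).

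In limma 417 genes passed, 182 higher and 235 lower, and the libraries of the groups did not overlap for 23.1% of tested genes against 10% by chance. The count fell to 87, 108 and 100 genes without young control replicate 1, 2 or 3, to 13 and 31 without aged control replicate 1 or 2, and to 102 and 75 without replicate 1 or 3 of the labelled-knockout libraries. Without their replicate 2 it rose to 1895. A fit of these 6 libraries alone called 14 genes. With immunoglobulin genes left out and the libraries rescaled, an alternative added after the data were seen, 139 genes were higher and 416 lower. The balance was the opposite without replicate 2 of the labelled-knockout libraries (1365 higher, 530 lower), without their replicate 1 (59 and 43), with array weights (4700 and 1647) and with a minimum of 5 FPKM (120 and 79). Without aged control replicate 3 it was 71 and 303. Of the 9 fits without 1 library, the calls of Cnmd and Col2a1 were lost in 8 and those of Snorc and Lcp1 in 2, while Atf3 passed in all 20 alternatives (log2 fold change 2.69 to 3.28).

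Of 12 chondrocyte markers 6 rose (10 adjusted over the list alone; camera adjusted p = 1.734e-08, adjusted p = 0.303 with an estimated correlation), among them Sox9, the regulator of cartilage formation, from 2.75 ± 0.916 to 31.1 ± 17.0 FPKM, Col9a1, and Col10a1, a collagen of hypertrophic cartilage whose exons overlap Nt5dc1, from 0.637 ± 0.43 to 55.6 ± 53.5 FPKM. In replicate 2 of these libraries Col2a1 was at 46.83 FPKM, below the 667.87 and 1665.46 FPKM of replicates 1 and 3. Of 22 osteogenic genes 6 rose (12 adjusted over the list alone; adjusted p = 5.651e-09, adjusted p = 0.303 with an estimated correlation), with Bglap at 794 ± 749 FPKM, Sp7 (osterix) at 25.1 ± 10.5 against 6.61 ± 0.303 FPKM and Col1a1 at 1173 ± 802 FPKM. Of 34 matrix genes 5 rose (16 adjusted over the list alone; adjusted p = 8.970e-09, adjusted p = 0.326 with an estimated correlation), including Col3a1 and Col1a2 at 1.46 and 2.12 on the log2 scale. Of 11 pericyte and smooth muscle genes 3 rose (8 adjusted over the list alone; adjusted p = 1.045e-05, adjusted p = 0.303 with an estimated correlation), namely Acta2, smooth muscle actin, from 9.02 ± 4.37 to 76.2 ± 42.4 FPKM, Tagln (log2 fold change 2.23, SE 0.28) and Mcam. In the 9 fits without 1 library, the calls of Col9a1, Col1a1 and Col1a2 were lost in 8, of Sp7, Col3a1 and Mcam in 7, of Col10a1 in 4, of Sox9, Bglap and Acta2 in 2 and of Tagln in 1.

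TGF-beta signalling genes were higher (5 of 26 rose, 11 adjusted over the list alone; adjusted p = 9.461e-05, adjusted p = 0.303 with an estimated correlation). The members that rose included Id3 (log2 fold change 1.59, SE 0.25) and Smad6 (1.61, SE 0.27), which are induced by BMP signals and, in the case of Smad6, inhibit them, and Tgfb2 (1.14, SE 0.24). In aged against young controls 3 of the 26 TGF-beta genes fell and their median was −0.55. That list was not called by camera (adjusted p = 0.069) but was called by fry (adjusted p = 0.0403). The immediate early and sorting stress list, of which 4 members were lower in the same aged controls than in young controls, was higher (5 of 24 rose, 7 adjusted over the list alone; adjusted p = 0.00357, adjusted p = 0.5 with an estimated correlation), with Atf3, Klf4 and Socs3. The senescence and secretory list was higher (4 of 21 rose and 1 fell, 11 and 2 adjusted over the list alone; adjusted p = 1.846e-04, adjusted p = 0.303 with an estimated correlation) through Gdf15, Igfbp6 and Ccl2, which was at 250 ± 90.1 FPKM. Niche factors were higher (1 of 20 rose, 4 adjusted over the list alone; adjusted p = 0.00644, adjusted p = 0.471 with an estimated correlation), the passing gene being the Notch ligand Jag1, at 15.7 ± 2.58 against 4.46 ± 0.855 FPKM. Cxcl12 lay at 0.53 (SE 0.29, adjusted p = 0.347), Vcam1 at 0.73 (SE 0.39), Il7 at 0.47 (SE 0.29), Lepr at −0.33 (SE 0.33), Cd47 at −0.14 (SE 0.25) and Kitl at 0.04 (SE 0.25), and none of these 6 passed. Adipogenic (0 of 21 passed, 0 adjusted over the list alone; adjusted p = 0.015, adjusted p = 0.465 with an estimated correlation), stromal identity (0 of 19, 1 rose adjusted over the list alone; adjusted p = 0.0217, adjusted p = 0.465 with an estimated correlation) and endosteal fibroblast lists (0 of 11, 2 rose and 1 fell adjusted over the list alone; adjusted p = 0.0146, adjusted p = 0.395 with an estimated correlation) were higher with no member passing, examples being Cebpd at 1.09, Hoxa10 at 1.01 and Clec3b at 2.29. The last 2 calls ended without replicate 2 of the labelled-knockout libraries (adjusted p = 0.206 and 0.374). Ribosomal protein genes, a list kept as a sign of RNA quality, were higher (0 of 40, 0 adjusted over the list alone; adjusted p = 0.00782, adjusted p = 0.708 with an estimated correlation), but without that replicate they were not called (median 0.06, camera direction lower, adjusted p = 0.123). Without 1 library at a time, the calls of Klf4, Socs3 and Ccl2 were lost in 8 of 9 fits, of Tgfb2 and Igfbp6 in 7, of Smad6 in 6, of Id3 and Gdf15 in 5, of Jag1 in 2 and of Atf3 in 0. Klf4 passed in 3 of 20 alternatives.

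Of 11 pan-leukocyte markers 7 fell (9 adjusted over the list alone; adjusted p = 3.906e-11, adjusted p = 0.303 with an estimated correlation), with Coro1a at 85.1 ± 65.1 against 1.69 ± 1.06 FPKM in the labelled-knockout libraries and Cd37 and Spi1 alongside Lcp1. B lineage markers were lower (1 of 10 fell, Mzb1, 4 adjusted over the list alone; adjusted p = 1.522e-05, adjusted p = 0.328 with an estimated correlation), and Cd79a lay at −2.37 (SE 0.62, adjusted p = 0.078). The immunoglobulin share of reads in these libraries, 0.203% to 23.1%, overlapped that of aged controls, 5.29% to 37.0%. Of the 235 genes that fell 19 were immunoglobulin genes. Ighv10-1 was at 1748 ± 1508 FPKM in aged controls and Ighv1-64 at 139 ± 68.6 FPKM, and both were listed at 0 in all 3 labelled-knockout libraries. Of 13 neutrophil markers 2 granule genes fell, Mpo and Ctsg (1 rose and 3 fell adjusted over the list alone; adjusted p = 2.502e-04, adjusted p = 0.303 with an estimated correlation). Megakaryocyte (0 of 5, 1 fell adjusted over the list alone; adjusted p = 0.015, adjusted p = 0.303 with an estimated correlation) and cell cycle lists (0 of 21, 0 adjusted over the list alone; adjusted p = 9.688e-04, adjusted p = 0.5 with an estimated correlation) were lower with no member passing, Itga2b at −2.88 and Mcm6 at −0.89. The mean cell cycle level was 1.15 to 2.38 in the labelled-knockout libraries and 2.99 in aged control replicate 1. Fry did not call that list (adjusted p = 0.390). Unfolded protein response genes were lower (1 of 21 fell, Hsp90b1, 1 adjusted over the list alone; adjusted p = 0.00357, adjusted p = 0.399 with an estimated correlation), as were interferon response genes (2 of 31 fell, Samd9l and Gbp7, 1 rose and 2 fell adjusted over the list alone; adjusted p = 0.0311, adjusted p = 0.492 with an estimated correlation). Mean unfolded protein response levels were 5.93, 6.17 and 6.10 in the labelled-knockout libraries, in the order of their immunoglobulin share (0.203%, 23.1% and 2.94%). Over the 9 fits without 1 library, the calls of Gbp7 and Hsp90b1 were lost in 8, of Spi1 and Ctsg in 7, of Samd9l and Coro1a in 6 and of Cd37 and Mzb1 in 2. The interferon and unfolded protein members thus lost their calls in most of these fits.

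**Figure D2:**
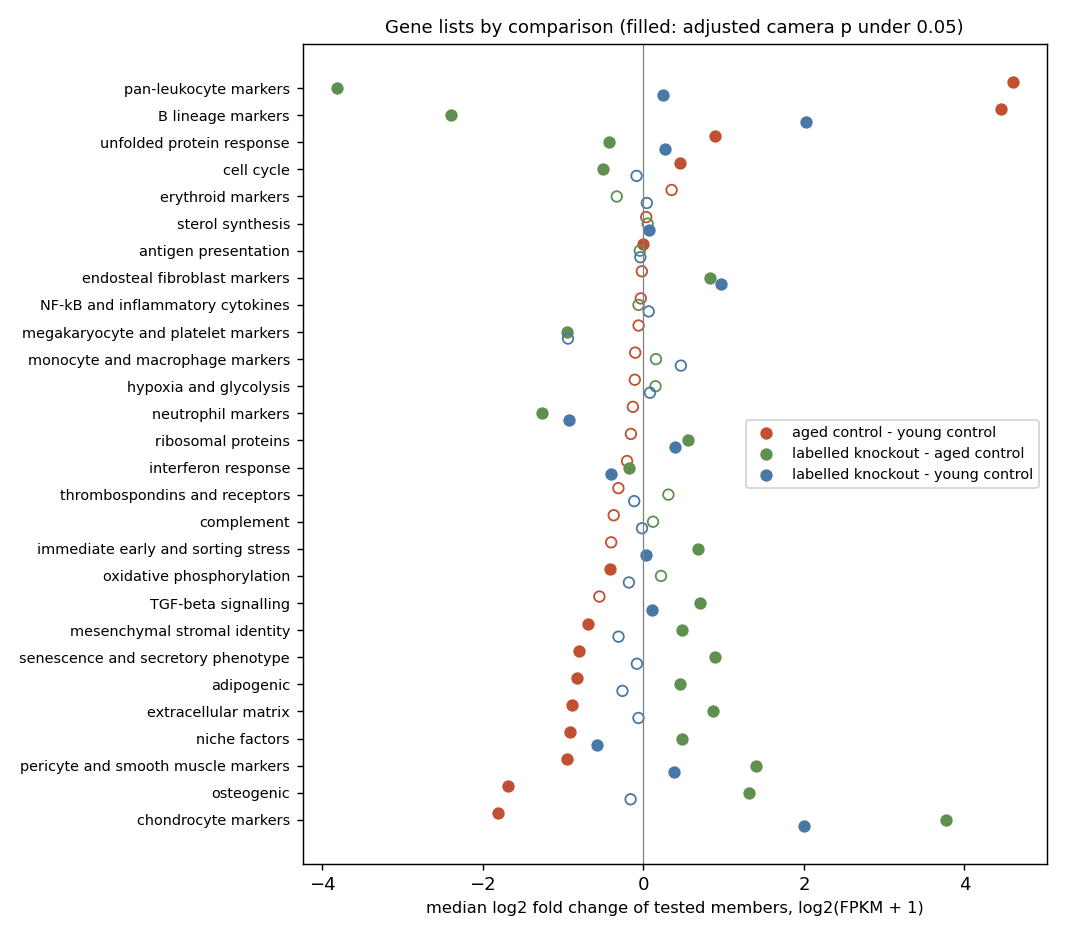
Median log2 fold change of the tested members of 28 gene lists (rows) in the 3 comparisons (colours), with filled points where the camera adjusted p was under 0.05. Osteogenic genes had a median of −1.69 in aged against young controls and 1.31 in the labelled-knockout libraries against aged controls.

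Labelled-knockout libraries and young controls differ in age and in labelled genotype, and their comparison asks how far the former lie from the young state. In limma 3 of 11988 genes passed, against 1035 at an unadjusted p under 0.05. Serpina1b, a gene of the alpha-1-antitrypsin family whose near-identical copies make single members uncertain, rose from 1.29 ± 0.537 to 12.8 ± 3.43 FPKM (log2 fold change 2.59, SE 0.27, adjusted p = 0.0161). The predicted gene Gm46329 averaged 24.4 ± 10.3 FPKM in young controls and was listed at 0 in all 3 labelled-knockout libraries (adjusted p = 5.14e-04). The RIKEN clone gene 2610300M13Rik fell from 8.39 ± 2.21 to 0.117 ± 0.169 FPKM (log2 fold change −3.06, SE 0.25, adjusted p = 0.00268). The last 2 fall outside the rule for named genes and were chosen after their values were seen. Both also lay lower than in every aged control and passed in all 20 alternatives, whereas Serpina1b passed in 8 of 20 and lost its call in 7 of 9 fits without 1 library. Without replicate 2 of the labelled-knockout libraries 37 genes passed, and without replicate 1 of them 5 did. Leaving out any young control, any aged control or replicate 3 of the labelled-knockout libraries gave 2 or 3 genes.

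Below the threshold, the smallest p-values included Ddit4l (log2 fold change −2.22, SE 0.32, adjusted p = 0.147), Lpl (−1.41, SE 0.23, adjusted p = 0.161), which stayed at 146 ± 26.9 FPKM, Nrgn (1.48, SE 0.24, adjusted p = 0.161) and 2 genes on chromosome 2. Gpr176 (118277110 to 118373419), an orphan receptor gene whose exons overlap Gm29232, lay at −1.54 (SE 0.26, adjusted p = 0.203) and Tmem87a (120355312 to 120404113) at 1.71 (SE 0.30, adjusted p = 0.214). Chondrocyte markers were higher than in young controls with no member passing over all genes (0 of 12; camera adjusted p = 6.509e-10, adjusted p = 0.486 with an estimated correlation; median 2.01). B lineage markers were also higher (0 of 10; adjusted p = 1.897e-07, adjusted p = 0.486 with an estimated correlation), as were endosteal fibroblast (0 of 11; adjusted p = 4.184e-07, adjusted p = 0.445 with an estimated correlation), pericyte (0 of 11; adjusted p = 4.619e-04, adjusted p = 0.486 with an estimated correlation) and unfolded protein response lists (0 of 21; adjusted p = 1.055e-04, adjusted p = 0.486 with an estimated correlation). The B lineage and endosteal calls rested on replicates 2 and 3. Mean log2 levels of B lineage markers were 1.97, 6.98 and 5.01 in the 3 labelled-knockout libraries against 1.33 to 3.00 in young controls, and those of endosteal markers 2.82, 4.27 and 4.22 against 2.56 to 2.83. Chondrocyte and pericyte levels were highest in replicates 1 and 3. Chondrocyte levels were 6.12, 3.93 and 7.52 against 3.77 to 4.64 in young controls. Pericyte levels were 3.73, 3.13 and 4.43 against 3.24 to 3.43, so replicate 2 lay below every young control on this scale. Relative to the median gene of each library, pericyte levels were 0.911, 0.647 and 1.55 against 0.392 to 0.647. On that scale replicate 2 lay at the level of the highest young control. Ribosomal proteins were higher (adjusted p = 1.476e-06, adjusted p = 0.579 with an estimated correlation), a direction that turned without replicate 2 of the labelled-knockout libraries (median −0.11, adjusted p = 0.415). TGF-beta signalling (adjusted p = 0.00212, adjusted p = 0.486 with an estimated correlation), immediate early (adjusted p = 0.00485, adjusted p = 0.579 with an estimated correlation), pan-leukocyte (adjusted p = 0.00981, adjusted p = 0.579 with an estimated correlation) and sterol synthesis lists (adjusted p = 0.0406, adjusted p = 0.579 with an estimated correlation) were called higher with medians of 0.10, 0.03, 0.25 and 0.07. Camera compares a list with the other genes, and the median gene lay at −0.16. These 4 calls therefore do not show a rise over young controls. Niche factors were lower (0 of 20; adjusted p = 0.00166, adjusted p = 0.554 with an estimated correlation), with Igf1 at −1.09 (SE 0.23) and Spp1 at −1.60 (SE 0.41), as were interferon response (adjusted p = 0.00167, adjusted p = 0.486 with an estimated correlation) and neutrophil lists (adjusted p = 0.0283, adjusted p = 0.579 with an estimated correlation), Samd9l at −1.41 (SE 0.30) and Ltf at −1.79 (SE 0.43). In this comparison 0 members of any list passed over all genes. Adjusted over the list alone, 2 endosteal fibroblast and 3 pericyte genes rose, 1 niche factor rose and 4 fell, 3 interferon response genes and 1 neutrophil gene fell, and 0 members of the other called lists passed. Among lists not called, 2 adipogenic genes fell, and 1 monocyte and macrophage marker rose and 2 fell. Osteogenic genes were not called (median −0.16, adjusted p = 0.839).

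Across the 3 comparisons 14, 19 and 13 of 28 lists passed camera with its preset correlation, and 0 passed with an estimated one. Fry, which tests whether a list moves on balance without comparing it with other genes, called 10, 7 and 0. Beyond the calls given above, the adipogenic and senescence lists with age lost theirs without replicate 2 of the labelled-knockout libraries (adjusted p = 0.0678 and 0.0618). The antigen presentation list lost its call under quantile normalization (adjusted p = 0.0745). Against aged controls, quantile normalization ended the niche factor, stromal identity and ribosomal calls (adjusted p = 0.0997, 0.172 and 0.459). Leaving out immunoglobulin genes ended the megakaryocyte call (adjusted p = 0.0606). Against young controls, the pan-leukocyte call ended under median-ratio rescaling and without that replicate (adjusted p = 0.0814 and 0.592). The immediate early call ended under quantile normalization (adjusted p = 0.121). The lists for thrombospondins and receptors, NF-kB and inflammatory cytokines, complement, hypoxia and glycolysis, erythroid cells, and monocytes and macrophages were not called with the values as deposited. Calls were also gained. Against young controls, the hypoxia and glycolysis and extracellular matrix lists were called under median-ratio rescaling (adjusted p = 0.0174 for both), with immunoglobulin genes left out (0.0234 and 0.0297) and without replicate 2 of the labelled-knockout libraries (0.00184 and 0.00505), and the megakaryocyte list was called under median-ratio rescaling (0.0427). Without that replicate, the antigen presentation and erythroid lists were called lower against aged controls (0.00897 and 0.0342), and the NF-kB list was called with age (0.0498). Median-ratio rescaling without it called the sterol synthesis list with age (0.0392).

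To ask how the 2 sets of changes relate, fold changes in the labelled-knockout libraries against aged controls were set beside those of aged against young controls. Pearson's r across 11988 genes, which are not independent, was −0.82. Both comparisons share the aged controls, and 100 simulations of unchanged groups gave a mean of −0.37 (range −0.98 to 0.81). The covariance was −0.69 against a simulated −0.08, a difference of −0.61. Both observed values lay within the simulated ranges, −1.04 to 0.173 for the covariance. The simulated SD was 0.471 for r and 0.149 for the covariance. Simulations with independent genes gave means of −0.50 and −0.10. The resampling drew libraries with replacement, so 1 library could fill several places, which the real groups do not allow. How many simulations were as extreme was not counted. An excess over unchanged groups was thus neither shown nor excluded by this measure. Of 308 genes that rose with age, 197 fell in the labelled-knockout libraries, where independent lists would share 6.04. Of 176 that fell with age, 59 rose, where 2.67 would be shared. The shared aged controls add to this excess by an unknown amount, since shared calls were not counted in the simulations and 3 libraries could not be split into separate sets. Among the 256 genes called in both were Ighv1-64, Ighv10-1, Igkv4-68, the cytoskeletal gene Slain1 and Fermt3, an integrin activator of blood cells. The lower mean of Thbs1 RNA in these libraries did not pass its test.

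**Figure D3:**
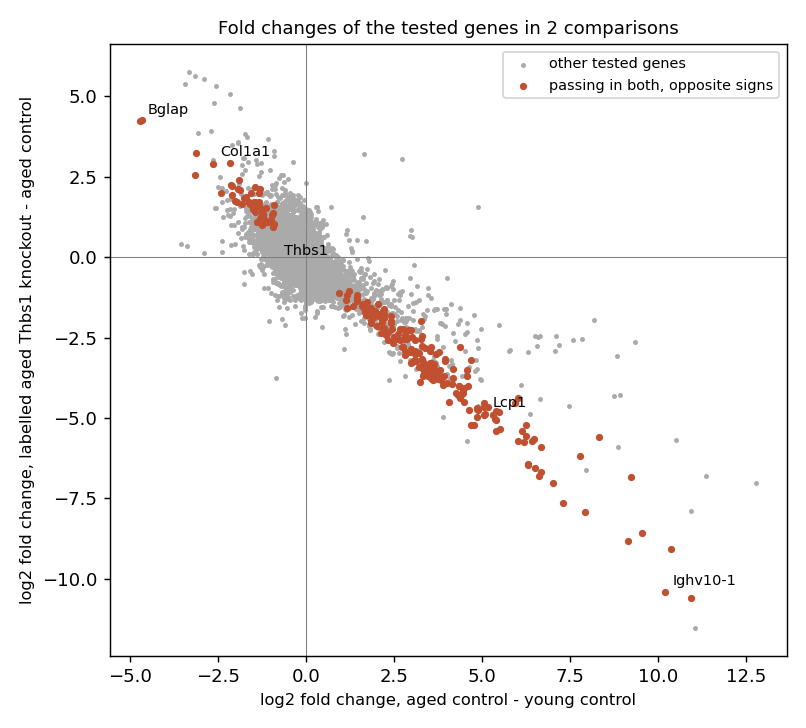
Log2 fold change of 11988 tested genes in aged against young controls (horizontal axis) and in the labelled-knockout libraries against aged controls (vertical axis), with red points for the 256 genes that passed in both in opposite directions. Bglap lay at −4.70 and 4.23, and Thbs1 at −0.83 and −0.15.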

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

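The alternative with immunoglobulin genes left out and the one joining median-ratio rescaling with the loss of labelled-knockout replicate 2 were chosen after the data were seen. Against 484 genes in aged and young controls, no filter gave 138, array weights 7419, a fit of the 6 libraries alone 2155, the replicate block 120, and median-ratio rescaling without labelled-knockout replicate 2 gave 1224. Leaving out 1 library gave 4 to 2729. Against 417 genes in the labelled-knockout libraries and aged controls, no filter gave 92, a minimum of 5 FPKM 199, array weights 6347, the 6 libraries alone 14, the replicate block 64 and the joint alternative 1311, and leaving out 1 library gave 13 to 1895. Against 3 genes in the third comparison, array weights gave 1414, the joint alternative 49, and leaving out 1 library 2 to 37. Array weights gave labelled-knockout replicate 2 a weight of 0.0543 and aged control replicate 1 a weight of 7.36. With an estimated correlation 0 lists were called in each comparison, and fry called 7 against 19 in the second and 0 against 13 in the third. No other alternative moved a list count by over 1.5 times. The fold-change correlation lay between −0.88 and −0.69 under every alternative. Replicate numbers did not pair the libraries: same-numbered libraries' deviations correlated at −0.288 to 0.302, and 2 of 9 correlated best with their own number. Thbs1 turned to 0.0939 without labelled-knockout replicate 1 (−0.33 without replicate 2; lowest over all alternatives −0.63, joint alternative). Of 2463 values of named genes under alternatives, 1794 kept direction and call, 563 lost the call, 89 gained it and 17 turned, all in genes that did not pass. Cd47 in aged against young controls turned to 0.21 (median-ratio rescaling), 0.14 (quantile normalization), 0.26 (immunoglobulin genes left out), 0.22 (joint alternative) and 0.0942 (without aged control replicate 3; lowest −0.32, without aged control replicate 2), and in labelled-knockout against aged controls to 0.0565 (without aged control replicate 2; −0.36 without aged control replicate 3; lowest −0.53, joint alternative). Kitl against aged controls turned to −0.0853, −0.25, −0.21 and −0.41 under the same 4, −0.15 without aged control replicate 1 and −0.11 without labelled-knockout replicate 2. Cxcl12 against young controls turned to 0.10, 0.14 and 0.0209 under the first 3 and 0.00734 without labelled-knockout replicate 3. Lepr against aged controls turned to 0.14 with array weights. The cause was not tested. The count-based alternative was not run, and depth, at 0.0543 to 0.0845 FPKM for 3 reads of a 2 kb gene, limits the lowest genes.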

Other observations

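Over the 9 libraries, 1 to 19 kappa variable genes were needed to reach 90% of kappa variable reads. The leading kappa gene took 64.7% to 74.2% in young controls, where immunoglobulin reads were few. A leading gene was thus not particular to aged controls. In young control replicate 3 it was Igkv15-103, at 66.1%. Igkv15-103 took 57.1% of kappa variable reads in aged control replicate 1 and 71.5% in replicate 3, but 16.0% in replicate 2, where 19 kappa genes were needed to reach 90%. Replicate 2 of the labelled-knockout libraries had Igkv14-126 in front, at 28.7%. Among heavy-chain variable genes Ighv10-1 took 64.9% in aged control replicate 1 and Ighv7-1 took 86.2% in replicate 3. Ighv7-1 also led in young control replicates 1 and 3 (66.8% and 97.4%) and in labelled-knockout replicate 3 (41.4%). Reads of single members are uncertain in such families. These genes were chosen after their values were seen.

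All tests below were chosen after the results were seen, except the counts of other splits of the libraries. The first pattern is the rise of immunoglobulin and leukocyte transcripts in aged controls. Of 14 plasma-cell markers, also chosen after the immunoglobulin reads were seen, 11 lay higher in all 3 aged controls than in all 3 young controls, against 7.02% of tested genes, with Jchain at 810 and Pou2af1 at 85.8 FPKM in aged controls; 5 of the 14 exceeded 20 FPKM in young controls and are thus also seen in young stromal libraries. Plasma cells in the sort are a candidate source of the immunoglobulin reads, and more such cells in aged marrow stays open as an untested biological reading. The same cells do not account for all pan-leukocyte genes, since the gap between mean log2 levels of the 2 lists ranged over 4.47 units within the aged controls, with Lcp1 at 116.91 FPKM in the library with the lowest immunoglobulin share and 10.59 FPKM in that with the highest. Cd52, also a pan-leukocyte marker, went the other way, at 112.58 FPKM in the former and 417.27 FPKM in the latter. These cells thus stay open as a source for part of that list. Labelled-knockout replicate 2 had Jchain at 964 FPKM but Lcp1 at 0.74 and Mzb1 at 0 FPKM, and which gates would have removed such cells is not given in the sources used here.

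The second pattern is the lower level of bone-forming and matrix genes in aged controls. Dilution by immunoglobulin reads does not account for it alone: with those genes left out and the libraries rescaled, the osteogenic median was −1.35 against −1.69 and the matrix median −0.50 against −0.89, with both lists still called. The passing members fell from 10 to 5 of 22 and from 4 to 2 of 34, so dilution stays open for part of the pattern. A lower share of stromal cells would lower stromal genes alike if no other sorted cells made them. The osteogenic median lay under the stromal identity median by a mean of −0.96 (SD 0.27 over the 3 aged controls). The identity median itself lay at −0.96, −0.49 and −0.68 in the 3 aged controls. The identity list holds Ly6a, which is also made by blood cells and rose with age. Whether other cells made further identity genes was not tested. The difference thus does not exclude a lower share, which stays open for all or part of the fall. After a trend on gene length was removed the osteogenic median was −1.69. What also stays open is a shift in which stromal cells were sorted, fewer bone-lineage cells, or lower expression per cell with age, which bulk libraries do not separate.

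The third pattern is a set of genes in which the labelled-knockout libraries lay apart from all 6 controls. With a gap of over 1 log2 unit, the only gap tried, there were 7 such genes: 2610300M13Rik, C5ar1, Gm3791, Gm46329, Gpr176, Nrgn and Serpina1b. Of the 84 splits of the 9 libraries into 3 and 6, 6 gave as many, so chance is not excluded; the 3 aged controls against the rest gave the most, 159, which points to a structure of the libraries that sets the aged controls apart. Gpr176, 150 kb from Thbs1, was the only one within 10 Mb of it (Fisher's exact two-sided p = 0.0665, odds ratio 17.0, 95% interval 0.367 to 142), so a chromosome segment inherited with the allele may have brought it, which this test leaves open; Tmem87a, also within 10 Mb, lay higher in all 3 labelled-knockout libraries (3.58 to 8.25 FPKM) than in all 6 controls (0.77 to 1.77 FPKM) by a gap under that size; the criterion for excluding such a segment was changed after this p was seen. Such a segment does not bring them all, since 14.3% lay within 10 Mb and the rest on 4 other chromosomes.

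Sets of 3 against 3 libraries make 10 splits, too few for a share under 0.05. For genes, 1 split, the real one, gave as many in each comparison, with 484 against at most 0 in the others for aged and young controls, 417 against at most 11 for labelled-knockout and aged controls, and 3 against at most 0 for labelled-knockout and young controls. For lists, 5 of 10 splits gave at least the 14 of aged against young controls and the highest other gave 19. In the other comparisons 1 split did, with 19 against at most 14 and 13 against at most 10.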
